A study of Danio rerio with 25 samples.

How the data were processed

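Small RNA was sequenced from the skin of male zebrafish (Danio rerio) at 5 ages, 6, 12, 24, 36 and 42 months, with 5 libraries per age. Per the labels, libraries were made with a small-RNA kit from total RNA. The titles give each of the 25 libraries its own number. The labels do not state in words that these are separate fish, and every p-value measures the spread between libraries. Replicates were numbered 1 to 5 within an age in the order of the sample records, and this order has no meaning.

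Per the submitters' processing notes, CASAVA 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9 were used, without a stated role or order. The counting step, the hairpin reference and the genome build are not given in the sources used here. The deposited table held raw read counts per microRNA hairpin, with no normalization. All values were whole numbers and the library totals differed, which was checked on the table. It had 346 hairpins, of which 38 had no count in any library. The table's names (dre-mir-23a-1) are written here as miR-23a-1, and a number after the last dash marks a genomic copy. No genome coordinates are printed, because no build was named.

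Copies of a single name held similar counts. Of 29 names with at least 2 copies and a mean summed count of at least 1000, 22 had copy totals within 1.1 times of each other. The 180 hairpins that share a name with another copy (115 of those tested) are therefore not independent measurements. Whether a read that matches several copies was divided among them or counted at each is not given in the sources used here. If it was counted at each, levels and shares with copies summed hold the same read up to as many times as there are copies, and library totals hold it too. Counts of changed hairpins are given for the table as deposited and, as an alternative added after the data were seen, with the copies summed into 217 names, of which 190 were tested.

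The strain label differed by age. Libraries of 6 and 24 months carried the same label, a cross of wild-type strains without a transgene. Those of 12, 36 and 42 months carried that label with a reporter transgene, flk:mCherry, pu.1:GFP and wt1a:GFP in that order. Strain and age therefore cannot be told apart in any comparison except 24 against 6 months. No batch or date was given in the labels.

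Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, hairpins with low counts were removed with filterByExpr by age group (minimum count 10), and 258 hairpins were tested with quasi-likelihood F tests. P-values were adjusted by Benjamini and Hochberg over all hairpins tested, at a threshold of 0.05. The tests were any difference among the 5 ages, a linear trend with age (log2 slope per 12 months), each of 12, 24, 36 and 42 months against 6 months, 42 against 36 months, and the trend on counts summed by microRNA number (124 families tested). All 25 libraries shared the estimate of the spread in each fit. Standard errors were computed from the log2 change and the F statistic. Levels are CPM, counts scaled to the library total multiplied by its TMM factor, with copies summed unless a copy is named. They are given as mean ± SD with n = 5 per age.

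In total 27 lists of microRNAs were defined by number. Their members are hairpins, so copies of a single name that share reads count as separate members. They were epidermal, miR-183 cluster, let-7, miR-99/100/125, miR-29, miR-17-92, miR-15/16, miR-34, inflammation, leukocyte, erythroid, endothelial, skeletal muscle, mesenchymal, cartilage, neural, pigment, liver and gut, Hox cluster, miR-23/24/27, miR-30, miR-26, miR-130/301/454, miR-221/222, miR-148/152, miR-101 and miR-430. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values for the trend, 24 against 6 and 42 against 6 months, 57 tests in all, adjusted together. Camera with an estimated correlation and fry were run beside it. Read totals and numbers of detected hairpins were compared among ages by a permutation test of the Kruskal-Wallis statistic with 100000 resamples.

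The tests, the lists, the alternative settings and the rule for naming microRNAs were fixed before the data were examined. The rule took the 10 of highest mean CPM. For the trend it took the 12 of smallest p in each direction. For 24 and for 42 against 6 months it took up to 10 per direction, and for the other pairs up to 5, with the largest change among those past the threshold whose CPM ranges did not overlap. It added 5 for the overall test, the members of highest mean CPM and all members past the threshold in the trend for each list, and up to 5 families per direction. Other names given below were chosen after their values were seen.

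Alternative settings were DESeq2 size factors, upper-quartile scaling and library size alone, no filter and a mean CPM of at least 100, DESeq2 1.42.0, limma-voom, robust estimation, only the 2 compared ages in the fit, age as rank or log2, a term for a transgene in the strain label, leaving out the 42-month group, and leaving out each library in turn. Summing copies and leaving out 3 doubted libraries (24 months replicate 3, 42 months replicates 2 and 5) were chosen after the data were seen.

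The procedure was tested on simulated data made from the fitted means and spreads, in 4 tables with 200 changed hairpins in all per test. Of 100 hairpins changed 2-fold, 77 were recovered in the trend, 72 at 24 against 6 months and 65 at 42 against 6 months. Of 100 changed 1.5-fold, 49, 32 and 35 were recovered. False calls numbered 11 of 831, 3 of 834 and 6 of 837 unchanged hairpins. Simulated hairpins were drawn independently, whereas real copies share reads. A shifted list was called in 19 of 20 simulated tables, with 2 of 360 other lists called. Figures were drawn with matplotlib.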

Results

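MicroRNA hairpins were counted in 25 small-RNA libraries of male zebrafish skin, 5 at each of 6, 12, 24, 36 and 42 months of age. The series title and its groups state the question, how skin microRNAs differ among 5 ages. Libraries held between 683884 reads (42 months replicate 2) and 5206505 reads (12 months replicate 5) on hairpins. Mean totals ranged from 3786530.0 ± 1137150.0 reads at 6 months to 1878600.0 ± 915895 at 42 months (SD, n = 5 each), with 3546020.0 ± 1316280.0 at 12, 3255522 ± 968100.0 at 24 and 3278810.0 ± 872458 at 36 months. The totals did not pass the permutation test among ages (p = 0.0974), nor did the number of hairpins with at least 1 count (p = 0.281, means 272.6 to 284.6). The number with at least 10 counts did differ (permutation p = 0.00474), with a mean of 237.8 ± 11.7 at 42 months and 253.4 ± 3.97 at 6 months.

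The skin libraries were dominated by few microRNAs. Taken by single hairpin over all 25 libraries, miR-10b, encoded within Hox clusters, took the largest share of counts, with 6.14% ± 1.13 for copy 1 and 6.11% ± 1.11 for copy 2 (SD, n = 25). The epithelial miR-205 followed with 5.80% ± 2.52, then the copies of miR-181a with 5.60% ± 1.51 and 5.57%. The next were miR-21 with 4.12% ± 1.79 and 4.05% ± 1.75, miR-462 with 3.94% ± 1.29, miR-22a with 3.83% ± 0.501 and miR-26b with 3.34% ± 0.685. With copies summed the order was miR-10b (12.3% ± 2.24), miR-181a (11.2% ± 3.01), miR-21 (8.17% ± 3.54), miR-205 and let-7a (5.26% ± 0.791). The 59 hairpins of the early-embryo miR-430 family were each too low to be tested. Summed as a family they were tested and called higher in the trend (slope 0.48 ± 0.16 log2 per 12 months, SE, adjusted p = 0.0252). The family was at 2.15 ± 1.37 CPM at 6 months, 5.396 ± 4.26 at 36 and 4.51 ± 3.22 at 42 months. It was not higher at 12 (1.84 ± 0.719) or 24 months (1.71 ± 1.07). The late means lean on 36 months replicate 4 (12.63 CPM) and 42 months replicate 2 (10.005 CPM). These levels are near the floor, and 42 months replicate 2, with 683884 reads in all, held only a few reads of the family. The other libraries held 2.32 to 5.73 CPM at 36 and 2.10 to 4.59 at 42 months.

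MicroRNA levels differed widely among the 5 ages. At an adjusted p under 0.05 edgeR called 99 of 258 hairpins for any difference among ages (135 at an unadjusted p under 0.05), and 69 of 190 names with copies summed. After miR-23a-2, miR-222b had the smallest p (adjusted p = 9.14e-06 for both). MiR-222b was at 270 ± 8.69 CPM at 6 months, 190 ± 35.9 at 24, 570 ± 130 at 36 and 456 ± 130 at 42 months. MiR-206, a microRNA of skeletal muscle, was at 251 ± 79.7 CPM at 6 months and 96.2 ± 41.6 at 36 months with its copies summed (adjusted p = 0.0013 for copy 2). MiR-27c-2, miR-93 and miR-16c also differed (adjusted p = 5.05e-04, 0.0013 and 0.00346).

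In the trend over all ages, members of the miR-23/24/27 clusters rose, with the highest list sum at 36 months (35047 ± 4318 CPM) and a lower one at 42 months (30634 ± 3008). MiR-23a increased from 934 ± 75.2 CPM at 6 months to 1364 ± 151 at 24, 1698 ± 102 at 36 and 1514 ± 186 at 42 months, a slope of 0.25 ± 0.03 log2 per 12 months for copy 1 (SE, adjusted p = 9.41e-06). MiR-27a rose by 0.19 ± 0.03 per 12 months (adjusted p = 1.37e-04) and miR-27c-1 by 0.30 ± 0.06. Of the 16 tested members of this list 9 rose, none fell, and 12 rose when adjusted over the list alone. The 16 include 4 copies of miR-23a and 2 of miR-27c, which hold similar counts and are not independent. The list as a whole passed camera (adjusted p = 2.92e-07), but not with an estimated correlation (adjusted p = 0.151). Under the planned settings and without each library in turn, between 7 and 13 members rose, miR-24 being the member most often lost.

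MicroRNAs known from inflammation also rose in the trend. MiR-21, which is induced in many inflamed and regenerating tissues, went from 61498 ± 5723 CPM at 6 months to 132152 ± 77227 at 42 months, and copy 1 rose by 0.36 ± 0.07 log2 per 12 months (SE, adjusted p = 3.2e-04). MiR-146a, a feedback inhibitor of innate immune signalling, went from 2319 ± 143.7 to 6545 ± 2423 CPM at 36 and 5837 ± 3193 at 42 months (slope 0.56 ± 0.09, adjusted p = 9.14e-05). MiR-146b rose by 0.77 ± 0.15 per 12 months (adjusted p = 3.94e-04), with 9406 CPM in 42 months replicate 1 against at most 1671 in the other libraries of that age. Without that library its slope, with copies summed, went from 0.80 to 0.44 (adjusted p = 7.68e-04). In this list 4 of 5 members rose, both copies of miR-21 among them, and miR-155 did not pass. The count was the same adjusted over the list alone, in every planned setting and without each library in turn. Camera gave an adjusted p of 0.00179, and 0.378 with an estimated correlation. At 24 against 6 months, the only pair with the same strain label, 0 of 5 members were called higher and 1 lower. Over the planned settings 0 to 2 were higher there. Against 6 months, 1 member was higher at 36 months and 4 at 42 months, ages whose labels name different transgenes.

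Among leukocyte microRNAs, the neutrophil and macrophage microRNA miR-223 rose by 0.55 ± 0.10 log2 per 12 months (SE, adjusted p = 3.2e-04), from 66.6 ± 21.8 CPM at 6 months to 265 ± 207 at 42 months, where replicate 1 held 615 and the others at most 269.6. The other 3 members did not pass, with slopes of -0.04 ± 0.06 for miR-142a, 0.02 ± 0.06 for miR-142b and -0.11 ± 0.06 for miR-150. The count was 1 of 4 over all hairpins and also when adjusted over the list alone. MiR-34a, which is induced by p53, rose by 0.59 ± 0.12 (adjusted p = 4.8e-04) from 19.03 ± 3.62 CPM to 53.3 ± 18.5 at 36 and 50.6 ± 56.4 at 42 months, and was the only tested member of its list. Its 42-month mean rested on 42 months replicate 1, with 149.6 CPM against 16.7 to 44.1 in the others. Without that library it was still called in the trend (slope 0.48 with copies summed, adjusted p = 8.54e-04).

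Of the let-7 cluster partners, both copies of miR-100 rose. MiR-100 increased from 3327 ± 337 CPM at 6 months to 4477 ± 318 at 24 and 5330 ± 1403 at 42 months, and copy 2 rose by 0.23 ± 0.04 log2 per 12 months (SE, adjusted p = 5.58e-05). Of the 10 members of the list of miR-99, miR-100 and miR-125 4 rose, also when adjusted over the list alone, and camera gave an adjusted p of 0.0104 (0.573 with an estimated correlation). Between 2 and 4 members rose over the planned settings, and between 2 and 7 without each library in turn. The other risers, miR-99-1 and miR-125c, were not called without the 42-month group (slopes 0.05 and 0.03, adjusted p = 0.468 and 0.8). MiR-222b rose by 0.35 ± 0.08 and miR-221 by 0.11 ± 0.04, 2 of 3 members of that list (3 adjusted over the list alone). Both calls were lost with a transgene term (adjusted p = 0.183 and 0.118), and without each library in turn 1 to 3 members rose. MiR-10a of the Hox cluster list rose by 0.14 ± 0.04 (1 of 10 members, also adjusted over the list alone), and upper-quartile scaling ended its call (adjusted p = 0.175). Without each library in turn 0 to 2 members of that list rose.

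**Figure D1:**
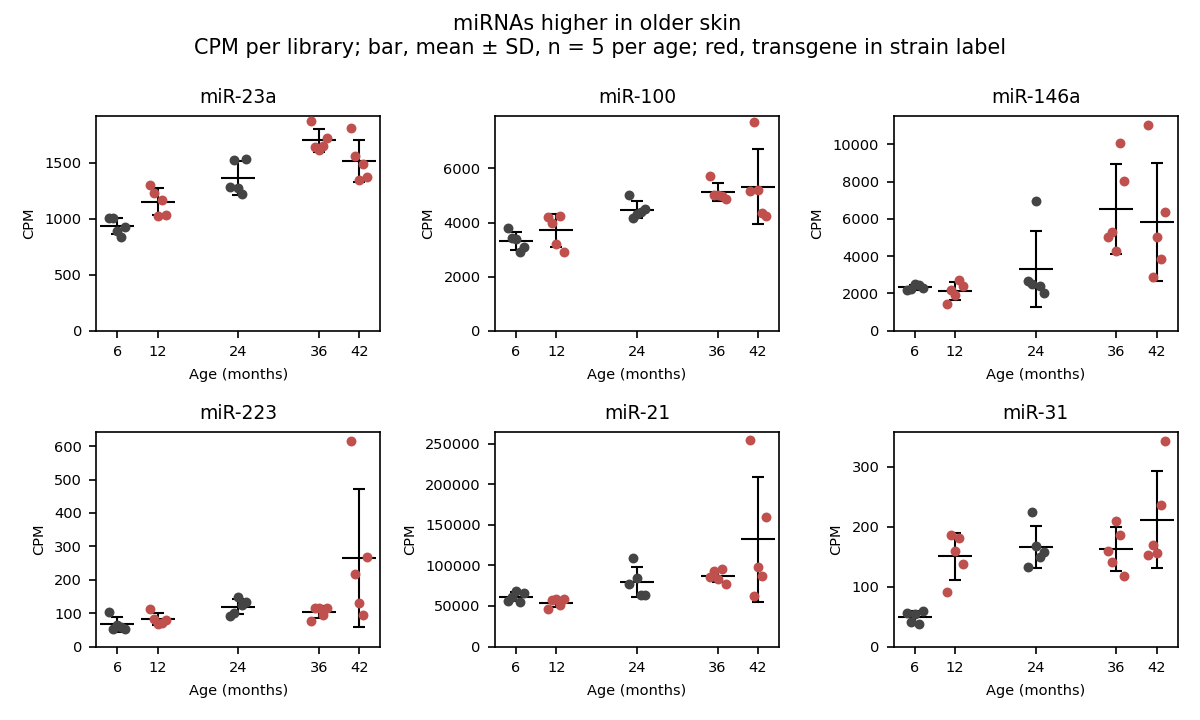
CPM of 6 microRNAs (vertical axes, copies summed) against age in months, with a dot per library, bars for mean ± SD (n = 5 per age) and red for ages whose strain label names a transgene. MiR-31 sits at 49.7 ± 9.89 CPM at 6 months and at 151 ± 38.8 or more at each later age, while miR-223 and miR-21 have their highest library at 42 months.

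Among the microRNAs that fell with age were miR-455 and miR-1388. MiR-455, known from cartilage, went from 840.4 ± 145.3 CPM at 6 months to 438 ± 81.5 at 24 and 342 ± 103 at 42 months, and copy 2 fell by 0.46 ± 0.07 log2 per 12 months (SE, adjusted p = 1.24e-05). MiR-1388 went from 1999 ± 294 to 1064 ± 292 and 634 ± 210.5 CPM at the same ages (slope -0.53 ± 0.08, adjusted p = 1.62e-05). MiR-107a fell by 0.33 ± 0.07 (adjusted p = 5.0e-04) and miR-107b by 0.46 ± 0.09 (adjusted p = 3.8e-04), while their relative miR-103 fell by 0.16 ± 0.04. The miR-107 family was at 1093 ± 164 CPM at 6 months, 386 ± 111 at 36 and 629 ± 151 at 42 months. In the edgeR fit with copies summed, miR-107a and miR-107b were higher at 42 than at 36 months (log2 changes 0.76 and 0.95, adjusted p = 0.0268 and 0.0423). MiR-181b-2 fell by 0.32 ± 0.07 and miR-181b-1 by 0.31 ± 0.07 (adjusted p = 0.00208 and 0.00278).

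Members of the miR-130 family that fell included miR-454b, from 1353 ± 249 CPM at 6 months to 794 ± 132.9 at 42 months (slope -0.23 ± 0.04, adjusted p = 1.67e-04), and miR-301b, from 29.97 ± 5.10 to 13.3 ± 7.54 (slope -0.39 ± 0.07, adjusted p = 3.2e-04). In this list 6 of 9 members fell and neither copy of miR-130c passed (slopes 0.0019 and -0.020), also when adjusted over the list alone, and camera gave an adjusted p of 0.0102 (0.483 with an estimated correlation). With a transgene term miR-130b, miR-301a, miR-301c and miR-454a were no longer called (adjusted p = 0.0917, 0.064, 0.0723 and 0.0698). Between 2 and 6 members fell over the planned settings and without each library in turn.

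Epithelial microRNAs that fell included miR-200b and miR-200c. MiR-200b went from 640 ± 85.4 CPM at 6 months to 421 ± 54.5 at 24 and 422 ± 54.5 at 42 months (slope -0.18 ± 0.04, adjusted p = 0.00124), and miR-200c from 1637 ± 201 to 1065 ± 189 and 1052 ± 159 (slope -0.16 ± 0.04, adjusted p = 0.00748). The keratinocyte microRNAs miR-203b and miR-205 did not pass, with slopes of -0.05 ± 0.07 and -0.02 ± 0.10. Of 9 epidermal members 5 fell, also when adjusted over the list alone, and camera gave an adjusted p of 0.0369 (0.6 with an estimated correlation). Without the 42-month group miR-200c missed the threshold (adjusted p = 0.0559). Over the planned settings 1 to 5 members fell (1 without the 42-month group, 2 with a transgene term), and without each library in turn 2 to 5. With copies summed 2 of 9 fell, and miR-200a, miR-141 and miR-429a were no longer called (adjusted p = 0.0817, 0.0794 and 0.132).

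Of the skeletal muscle microRNAs, miR-206 and miR-1 fell in the trend, with a slope of -0.47 ± 0.11 for miR-206-1 (SE, adjusted p = 0.00197). Of 9 members 4 fell, also when adjusted over the list alone, and camera gave an adjusted p of 0.0369 (0.617 with an estimated correlation). Both copies of miR-1 left the count with copies summed (slope -0.32, adjusted p = 0.0503), and the abundant miR-133a-1 did not pass (slope -0.15 ± 0.09). Over the planned settings 1 to 4 members fell (1 of 6 tested at a mean CPM of at least 100), and without each library in turn 2 to 4. At 42 against 6 months 2 of 9 members were lower (0 with limma-voom, with only the 2 ages in the fit or without 42 months replicate 1), and camera did not pass (adjusted p = 0.431). In the miR-30 family miR-30a and miR-30b fell (slopes -0.67 ± 0.18 and -0.11 ± 0.04, 2 of 5 members, 3 adjusted over the list alone). MiR-148 and miR-152 both fell (slopes -0.15 ± 0.05 each, also adjusted over the list alone). None of these 4 kept its call with a transgene term (adjusted p = 0.158, 0.199, 0.0698 and 0.146). Without each library in turn the miR-30 count was 0 to 3 (0 without 6 months replicate 5) and the count of miR-148 and miR-152 was 0 to 2 (0 without any of 6 libraries). In the neural list miR-124-1 and miR-124-2 rose (slopes 0.61 ± 0.22 and 0.70 ± 0.24, 2 of 16, and 0 adjusted over the list alone), but without 42 months replicate 5 their slopes were 0.03 and 0.11 (adjusted p = 0.92 and 0.755).

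Many lists held no or few calls in the trend. Let-7h was called lower among 18 let-7 members and miR-93 among 17 members of the miR-17-92 list, and neither list kept a call adjusted over the list alone. With a transgene term neither was called (adjusted p = 0.0813 for both). The let-7 count was 0 to 7 over the planned settings (7 without the 42-month group) and 0 to 3 without each library in turn. None of the members passed in the lists erythroid (2), endothelial (2), mesenchymal (7), cartilage (1), pigment (2), liver and gut (3), miR-15/16 (9), miR-26 (4), miR-29 (3) and miR-101 (2), also adjusted over the list alone. The miR-183 cluster had 0 of 3 calls, but all 3 were lower when adjusted over the list alone, with slopes from -0.16 to -0.10. Over the planned settings up to 3 members of the miR-15/16 list and up to 2 of the miR-183 cluster fell, and without 12 months replicate 3, 2 of 3 miR-29 members rose.

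**Figure D2:**
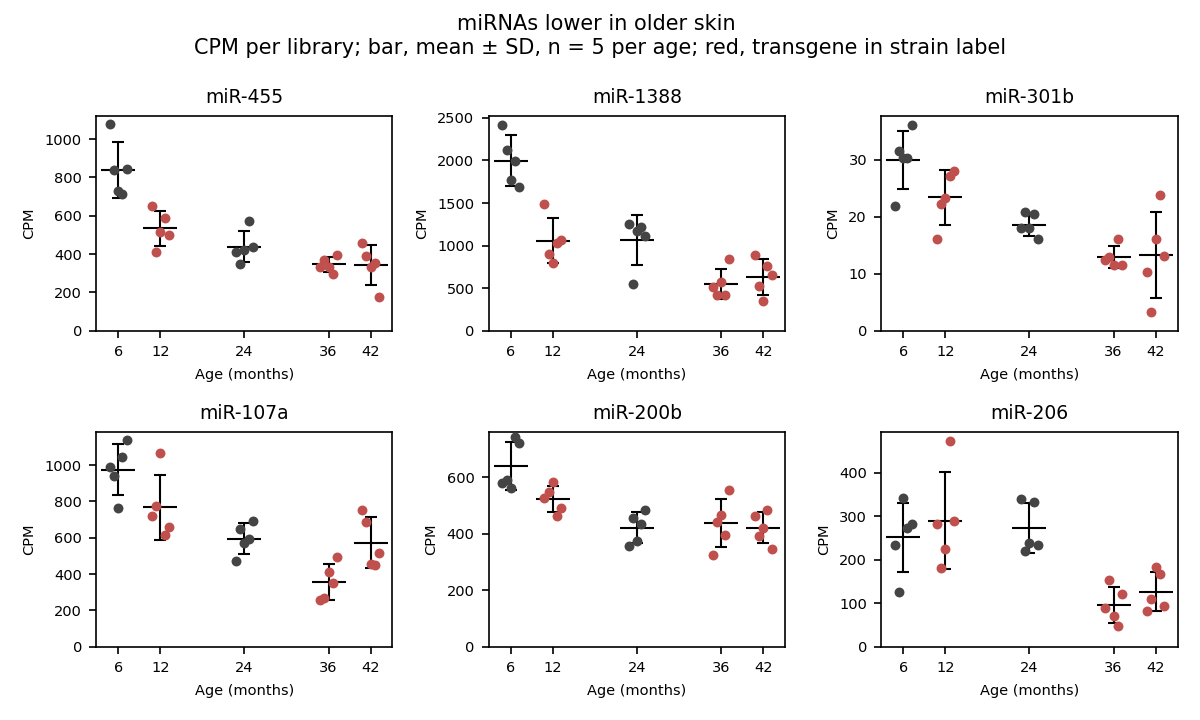
CPM of 6 microRNAs (vertical axes, copies summed) against age in months, with a dot per library, bars for mean ± SD (n = 5 per age) and red for ages whose strain label names a transgene. MiR-1388 goes from 1999 ± 294 CPM at 6 months to 634 ± 210.5 at 42 months, and miR-206 is lower at 36 and 42 months than at the earlier ages.

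Over the trend 65 of 258 hairpins passed in edgeR, 31 rising and 34 falling (97 at an unadjusted p under 0.05), and 42 of 190 names passed with copies summed, 25 rising and 17 falling. Upper-quartile scaling gave 20 rising and 44 falling, and library size alone 25 and 46. A transgene term, which cannot separate 3 different lines, gave 39 calls, 36 of them among the 65, and without 6 months replicate 4 or 6 months replicate 5 the calls were 42, all among the 65. At family level 34 families passed (27.4% of those tested), 15 rising and 19 falling, led by miR-455 (slope -0.41 ± 0.05, adjusted p = 1.86e-06) and miR-1388 (slope -0.54 ± 0.07). Families miR-454, miR-107 and miR-206 also fell, by 0.24, 0.35 and 0.48 per 12 months. The rising families of smallest p were miR-100 (0.22 ± 0.04, adjusted p = 7.55e-05), miR-146 (0.59 ± 0.10), miR-23 (0.17 ± 0.03), miR-223 (0.54 ± 0.10) and miR-21 (0.35 ± 0.07). A transgene term gave 22 families, 19 of them among the 34, and leaving out the 3 doubted libraries gave 22, with 17 among the 34.

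Skin at 24 months was compared with skin at 6 months, the only pair with the same strain label. Of the rises in which the CPM ranges did not overlap, that of miR-31, a microRNA of keratinocytes, was the largest, from 49.7 ± 9.89 to 167 ± 34.7 CPM (log2 change 1.75 ± 0.24, SE, adjusted p = 5.38e-05). The clustered miR-132-2 and miR-212, known from neurons and immune cells, rose by 0.92 ± 0.23 and 0.62 ± 0.20, and miR-210, which is induced by hypoxia, by 0.62 ± 0.22 (adjusted p = 0.00525, 0.0249 and 0.0423). MiR-210 and miR-212 were not called without 6 months replicate 5 (adjusted p = 0.11 and 0.0684) and several other libraries. MiR-23a-2 rose by 0.59 ± 0.10 and miR-27a by 0.49 ± 0.11, and 7 of 16 miR-23/24/27 members rose (10 adjusted over the list alone; camera adjusted p = 1.18e-05, and 0.151 with an estimated correlation).

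Of the falls of single hairpins in which the CPM ranges did not overlap, that of miR-455-2 was the largest (change -1.35 ± 0.20, SE, adjusted p = 1.01e-04). MiR-30a fell by more with ranges that overlapped (change -1.73 ± 0.46, adjusted p = 0.00856). In the fit with copies summed miR-455 changed by only -0.83 ± 0.19. That was less than miR-731 (-1.13), miR-462 (-1.09) and miR-181b (-1.06) in the same fit. The clustered miR-731 and miR-462, known from the antiviral response of fish, fell by 1.27 ± 0.23 and 1.24 ± 0.24, with miR-462 at 57866 ± 11248 CPM at 6 months and 24514 ± 8320 at 24 months. MiR-181b-2 fell by 1.21 ± 0.25 and miR-181a-2 by 0.88 ± 0.18. MiR-155, the inflammation member, fell by 1.08 ± 0.36 (adjusted p = 0.0304; 0.0557 with copies summed), while none of its 4 partners passed (0 to 2 over the planned settings).

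Of 9 epidermal members 6 fell at 24 months, also when adjusted over the list alone, among them miR-203b from 33803 ± 4508 to 19651 ± 4760 CPM (change -0.78 ± 0.17, adjusted p = 0.00205) and miR-200c (change -0.63 ± 0.14). Camera gave an adjusted p of 0.00251 for this list, and 0.552 with an estimated correlation. In the miR-15/16 family, known for holding back cell division, 7 of 9 members fell (8 adjusted over the list alone), with miR-16c going from 1616 ± 125.1 to 1093 ± 89.3 CPM. Camera gave 4.89e-04 for that list (adjusted p = 0.376 with an estimated correlation). The miR-15/16 count was 4 to 7 over the planned settings and 5 to 7 without each library in turn. Let-7 had 3 of 18 members lower (1 adjusted over the list alone; camera adjusted p = 0.00204, and 0.573 with an estimated correlation). Without single libraries between 1 and 12 let-7 members were lower (12 without 24 months replicate 2), and between 3 and 6 epidermal members (3 without 24 months replicate 1). All 3 liver and gut microRNAs were called higher (changes 1.84 to 2.17, with ranges that overlapped), also adjusted over the list alone, but without 24 months replicate 3, which held 38083 CPM of miR-192, none was (miR-192 change 0.73 ± 0.49, adjusted p = 0.369).

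In total 65 of 258 hairpins passed at 24 months in edgeR, 23 higher and 42 lower (92 at an unadjusted p under 0.05), and 36 of the 65 had CPM ranges that did not overlap. With copies summed 45 of 190 names passed, 22 higher and 23 lower. The split depended on the scaling, with 33 higher and 36 lower under DESeq2 size factors, 26 and 25 under upper-quartile scaling, and 26 and 32 under library size. The median change of all hairpins was 0.05 under TMM and 0.18 under upper-quartile scaling, and the changes above are relative to the former. Library size moved it to 0.15 here and, at 12 months, from -0.03 to 0.13. Without 6 months replicate 5, 43 hairpins passed.

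At 12 months few microRNAs differed from 6 months. MiR-31 rose from 49.7 ± 9.89 to 151 ± 38.8 CPM (log2 change 1.60 ± 0.24, SE, adjusted p = 2.0e-04) and was called in every setting run. MiR-1388, miR-462, miR-731, miR-455-2 and miR-103 were called lower, with changes of -0.92 ± 0.25, -0.90 ± 0.24, -0.80 ± 0.23, -0.76 ± 0.20 and -0.41 ± 0.11. None of these 5 passed with copies summed (adjusted p from 0.0974 to 0.163) or with upper-quartile scaling (adjusted p from 0.171 to 0.227). The fit with copies summed had its own TMM scaling, which also moved hairpins without copies. There miR-31 changed by 1.69, miR-1388 by -0.83, miR-462 by -0.80, miR-731 by -0.70 and miR-103 by -0.31. In edgeR 10 of 258 hairpins passed, 3 higher and 7 lower (69 at an unadjusted p under 0.05), of which 6 had ranges that did not overlap. DESeq2 called 21, limma-voom 18, a fit of only the 2 ages 21, upper-quartile scaling 1, and the split was 4 and 3 with DESeq2 size factors and 11 and 2 with library size. Without 6 months replicate 3, 12 passed, and without any other library of these ages 1 to 6. Of the lists, miR-30 and miR-17-92 had 1 member lower each, while neural had 0 of 16 members higher over all hairpins and 12 adjusted over the list alone. The neural count was 0 to 9 over the planned settings (9 with only the 2 ages in the fit) and 13 of 17 without the doubted libraries. The strain labels of these ages differ.

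At 36 months miR-31 (change 1.71 ± 0.24), miR-146a (1.497 ± 0.34) and miR-34a (1.48 ± 0.43, SE, adjusted p = 0.0115) were higher than at 6 months. MiR-2189 rose from 3.22 ± 1.73 to 18.8 ± 10.7 CPM and miR-726 from 3.27 ± 0.913 to 10.1 ± 4.19. MiR-2185 went from 274 ± 34.5 to 27.4 ± 35.9 CPM, with a change of -3.34 ± 0.93 for copy 1 (adjusted p = 0.00876), and 3 of the 5 libraries of 36 months held 2.26 to 4.21 CPM of it. MiR-107b (change -1.94 ± 0.27) and miR-1388 (change -1.85 ± 0.26) were lower.

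Of the miR-23/24/27 members 13 of 16 rose at 36 months, also when adjusted over the list alone, and 8 of 18 let-7 members fell, also adjusted over the list alone. Many of these members are copies of a single name. With copies summed miR-23a, miR-24, miR-27a, miR-27b and miR-27c were called higher, and miR-23b, miR-27d and miR-27e were not. Of let-7, only let-7c, let-7e and let-7g were called lower in that fit. Skeletal muscle, epidermal and miR-130 family members fell in 2 cases each (2, 4 and 2 adjusted over the list alone). Without each library in turn the epidermal count was 1 to 4 and the miR-130 family count 1 to 2, while the let-7 count was 6 to 8. Over the planned settings the miR-23/24/27 count was 8 to 13. In total 65 of 258 hairpins passed in edgeR, 28 higher and 37 lower (87 at an unadjusted p under 0.05), and 47 of them had ranges that did not overlap. With copies summed 37 of 190 names passed, and 43 hairpins among those of at least 100 CPM. The strain labels differ between 36 and 6 months.

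At 42 months the oldest skin held 212 ± 81.2 CPM of miR-31, a change of 2.09 ± 0.24 (SE, adjusted p = 3.07e-06) from 6 months. MiR-146a rose by 1.33 ± 0.34, miR-27c-1 by 0.77 ± 0.18, miR-23a-2 by 0.72 ± 0.10 and miR-100-1 by 0.69 ± 0.14. MiR-216b went from 65.0 ± 25.4 to 18.7 ± 5.03 CPM (change -1.80 ± 0.46, adjusted p = 0.00447), and its cluster partner miR-216a from 15.6 ± 4.03 to 5.27 ± 2.60 (change -1.62 ± 0.56, adjusted p = 0.0359; 0.0798 without 42 months replicate 4, and also lost without 42 months replicates 1 and 5 and 6 months replicates 1, 2 and 5). MiR-1388, miR-455-2, miR-107b and miR-181b-2 fell by 1.66 ± 0.25, 1.52 ± 0.20, 1.06 ± 0.27 and 1.05 ± 0.25, and miR-454a by 0.88 ± 0.14. With copies summed miR-455 and miR-181b changed by -1.16 ± 0.19 and -0.88 ± 0.28. Part of this difference lies in the TMM scaling of that fit. In it miR-31, miR-1388 and miR-454a, which have no copies to sum, changed by 2.27, -1.50 and -0.74.

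Of the lists at 42 months, inflammation had 4 of 5 members higher (also adjusted over the list alone; camera adjusted p = 0.0104, and 0.552 with an estimated correlation) and miR-23/24/27 had 7 of 16 higher (7 adjusted over the list alone; 4.19e-06, and adjusted p = 0.151 with an estimated correlation). In the list of miR-99, miR-100 and miR-125 5 of 10 were higher, also adjusted over the list alone (camera adjusted p = 0.00727, and 0.573 with an estimated correlation). That count was 2 to 5 over the planned settings (2 with only the 2 ages in the fit) and 3 to 5 without each library in turn. Epidermal members fell in 6 of 9 cases, also adjusted over the list alone, with camera at 0.00842 (adjusted p = 0.573 with an estimated correlation), and in 4 to 6 cases over the planned settings and without each library in turn. In the miR-130 family list 5 of 9 fell, 7 adjusted over the list alone, with camera at 0.00121 (adjusted p = 0.297 with an estimated correlation), and 2 to 5 fell over the planned settings. Neural microRNAs were higher in 6 of 16 cases (13 adjusted over the list alone; camera adjusted p = 0.0212, and 0.668 with an estimated correlation), with 0 to 11 over the planned settings and 0 to 13 without each library in turn. Without 42 months replicate 5, which held 658 CPM of miR-124 against 9.77 to 30.8 in the others of its age, 0 of 17 passed, and miR-124-1 changed by 0.25 ± 0.47 (adjusted p = 0.754). Many neural members are copies of miR-9 or miR-124. With copies summed and all libraries, edgeR called miR-124 and miR-9 (adjusted p = 0.00425 and 0.0413). MiR-219, miR-137 and miR-138 did not pass (adjusted p = 0.112, 0.314 and 0.979).

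In total 62 of 258 hairpins passed at 42 months in edgeR, 30 higher and 32 lower (100 at an unadjusted p under 0.05), and 31 had ranges that did not overlap. With copies summed 52 of 190 names passed, 29 higher and 23 lower. The strain labels differ, and read totals were lowest at this age.

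Between 36 and 42 months few microRNAs differed. MiR-2185 was higher at 42 months, 341 ± 219.2 against 27.4 ± 35.9 CPM (change 3.64 ± 0.95 for copy 1, SE, adjusted p = 0.0264). It was near absent from 36 months replicates 2, 3 and 4, at 2.26 to 4.21 CPM, which lowers the mean of that age. Let-7c rose from 2355 ± 213 to 4001 ± 1350 CPM (change 0.77 ± 0.18 for copy 2). MiR-30a, miR-135c-2 and miR-454a were lower, with changes of -2.61 ± 0.59, -1.85 ± 0.51 and -0.61 ± 0.14. In edgeR 10 of 258 hairpins passed, 7 higher and 3 lower (69 at an unadjusted p under 0.05), 8 of them with ranges that did not overlap. Without 36 months replicate 4, 1 passed, and let-7c-2 was lost (adjusted p = 0.0715). Without 42 months replicate 1, 4 passed, and let-7c-2 was lost as well (adjusted p = 0.0995). Without 42 months replicates 3, 4 and 5 in turn, 21, 29 and 18 passed. In a fit of only these 2 ages edgeR called 0 of 255 (65 at an unadjusted p under 0.05), while DESeq2 on all ages called 35 and limma-voom 9. These ages carry different transgenes.

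Hairpins near absent from single libraries were found after the values were seen. MiR-725 held 31.2 to 57.9 CPM in 12 months replicate 2, 36 months replicate 3 and 42 months replicates 3 and 4, and at least 2435 CPM in each of the other libraries. It did not differ among the ages (adjusted p = 0.689 with copies summed).

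**Figure D3:**
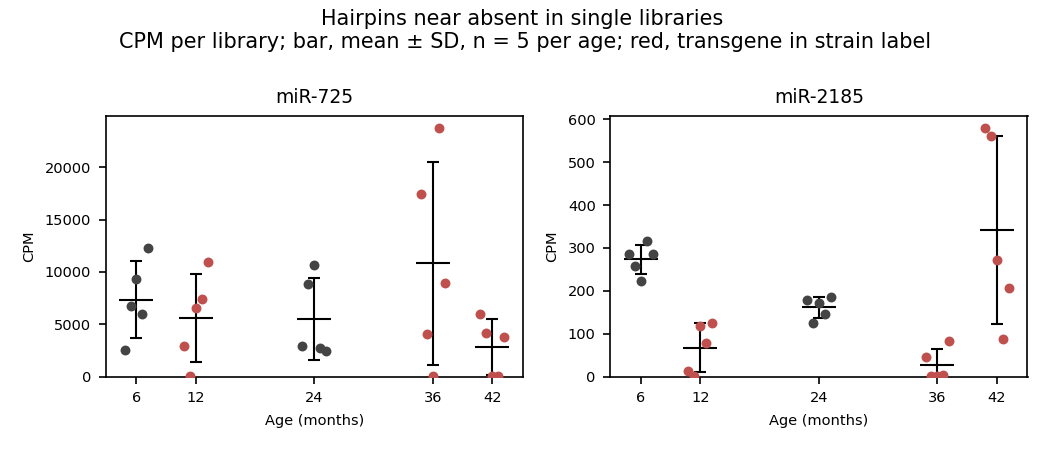
CPM of miR-725 and miR-2185 (vertical axes, copies summed) against age in months, with a dot per library, bars for mean ± SD (n = 5 per age) and red for ages whose strain label names a transgene. For miR-725, 4 libraries lie at 31.2 to 57.9 CPM and the others at 2435 CPM or more.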

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

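The tests of read depth, of leukocytes, of a single library and of miR-725 given here were chosen only after the results were seen. In 135 measures (the named microRNAs with copies summed, the summed lists, and numbers of hairpins detected) and 675 groups of 5 libraries, 67 values lay apart from the others of their age. A value was taken as apart when its gap to the nearest library was over 0.71 of the group's range (Dixon's criterion). Chance alone gives about 1 in 20 such groups, and the measures overlap. Values are CPM, each followed by the range of the other 4 libraries of its age.

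In 6 months replicate 1 these were miR-101a at 4789 (7391 to 8286), miR-125c at 1272 (661 to 772), miR-216b at 109 (44.7 to 59.4), miR-223 at 105 (51.3 to 63.3) and miR-301c at 39.7 (68.3 to 73.0). That library also held miR-30e at 3285 (4399 to 4806), the summed miR-101 list at 4907 (7541 to 8471) and the summed miR-430 list at 4.53 (1.12 to 1.94). In 6 months replicate 2 it was let-7c at 4512 (3386 to 3666). In 6 months replicate 3 these were miR-150 at 672 (375 to 444), miR-25 at 2807 (3145 to 3228) and the summed epidermal list at 83639 (112284 to 122131).

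In 12 months replicate 1 these were let-7a at 38426 (53134 to 57089.5), miR-103 at 329 (284 to 296), miR-125a at 2669 (1125 to 1492), miR-125c at 1436 (674 to 765) and miR-181b at 8972 (3442 to 4911). That library also held miR-30d at 10786 (6082 to 6286), miR-92a at 41500.4 (20832 to 26817), the summed let-7 list at 59424 (79356 to 86550.2) and the summed miR-30 list at 17470.3 (12136 to 13640.3). In 12 months replicate 3 it was miR-29b at 360.3 (76.3 to 121). In 12 months replicate 5 it was miR-99 at 450.5 (711 to 786).

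In 24 months replicate 1 it was the number of hairpins with at least 1 count at 286 (275 to 278). In 24 months replicate 2 these were miR-133a at 3994 (9922 to 11429), miR-1388 at 551 (1118 to 1257), miR-150 at 268 (406 to 439.8), miR-26a at 31494 (42916 to 46095) and the summed skeletal muscle list at 5053 (11153 to 13641). In 24 months replicate 3 these were miR-101b at 596 (172 to 258), miR-122 at 1826 (137.9 to 392), miR-146a at 6981 (2030.5 to 2687), miR-146b at 919.8 (336 to 491) and miR-192 at 38083 (2278 to 5652). That library also held miR-194a at 655 (35.2 to 123), miR-216a at 93.5 (4.84 to 19.1), miR-216b at 224 (22.0 to 58.1), miR-29b at 426 (83.7 to 176) and the summed liver and gut list at 40567 (2452 to 6167). In 24 months replicate 5 these were miR-101a at 4834 (9279.6 to 10712), miR-126b at 1616 (3203 to 3806), miR-138 at 57.3 (34.4 to 36.5), miR-27b at 10701 (12891 to 13758) and miR-731 at 3503 (1879 to 2230.1). That library also held the summed miR-101 list at 5006 (9499.7 to 11308).

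In 36 months replicate 1 these were miR-100 at 5736 (4886 to 5024), miR-140 at 653 (427 to 466), miR-204 at 45885 (32480.1 to 34983), miR-454a at 128 (157 to 165) and the summed cartilage list at 653 (427 to 466). That library also held the summed pigment list at 45885 (32480.1 to 34983). In 36 months replicate 2 these were miR-1 at 173 (59.6 to 84.1) and miR-210 at 871 (468 to 535). In 36 months replicate 3 it was miR-27a at 3551 (2888 to 3017). In 36 months replicate 5 it was miR-216a at 17.5 (10.2 to 12.3).

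In 42 months replicate 1 these were miR-146b at 9406 (549 to 1671), miR-34a at 149.6 (16.7 to 44.1) and the summed miR-34 list at 151 (16.7 to 47.6). In 42 months replicate 2 these were miR-100 at 7709 (4230.4 to 5204), miR-182 at 7680.2 (4314 to 4905), miR-205 at 169036 (34405 to 63352), the summed epidermal list at 208207 (61342 to 99819.7) and the summed miR-183 cluster list at 8366 (4899 to 5579). In 42 months replicate 4 it was miR-216b at 9.77 (19.6 to 21.7). In 42 months replicate 5 these were miR-124 at 658 (9.77 to 30.8), miR-9 at 998 (88.0 to 220.4) and the summed neural list at 1740.0 (145.3 to 299).

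The first pattern is the set of hairpins called in the trend, 65 of 258, since age and strain label move together. Fewer reads at 42 months would need the calls to depend on that group, but 42 of the 65 were also called without it. A transgenic line in place of age stays open. Of the 45 names called at 24 against 6 months, which share a label, 66.7% had the same sign in the trend over 12, 36 and 42 months, and 14 of 100 permutations of age gave as much (highest 77.8%). Age itself may also underlie these calls, and was not separated from line.

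The second pattern is the rise of miR-21, miR-146a, miR-146b, miR-223 and miR-34a. More leukocytes of all kinds would raise miR-142a, miR-142b and miR-150 as well. A cut of 0.296 log2 per 12 months was chosen for them after the results were seen, as 1/2 of the median slope of the 5 names (0.593). Their highest slope plus 2 standard errors was 0.163. This argues against a rise of that size in these microRNAs, while a smaller one is not excluded. A single library at 42 months is argued against because all 5 names were called without 42 months replicate 1, with slopes of 0.31 to 0.54. A change in particular immune cells or in the levels per cell, with age or line, could underlie the rise and was not tested.

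The third pattern is hairpins near absent from single libraries. Low depth is argued against, since the smallest low library would hold 9727 reads of miR-725 at its median CPM and the low libraries held 73 to 239. The line as a whole is argued against, since all 3 lines with a low library also had one at 1000 CPM or more. The 4 low libraries were among 15 with a transgene in the label and 0 among 10 without. With only 4 low libraries this split may be chance, and it was not tested. A sequence variant in some fish of these lines is a candidate explanation that was not tested either. MiR-2185 held 2.12 to 4.21 CPM in 12 months replicate 2 and 36 months replicates 2, 3 and 4, against a median of 145.6, and miR-735 had 0 reads in 42 months replicate 5, where 452 were due at its median.

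Labels of the libraries were regrouped 100 times, the real grouping included. Only the real grouping gave as many calls for any difference among ages (99 calls, highest other 12, 1 of 100 as large) and for the trend (65, highest other 5, 1 of 100). The same held for 12 months (10, highest other 2), 24 months (65, highest other 28), 36 months (65, highest other 14) and 42 months (62, highest other 42) against 6 months, with 1 of 100 each. It held for families too (34, highest other 6, 1 of 100). With 100 groupings no smaller share can be reached, so chance was unlikely there but not excluded. For 12 months the count itself was 1 with upper-quartile scaling and 3 with copies summed. Chance could account for 42 against 36 months, with 10 calls, 14 in the highest other grouping and 5 of 100 as large. It could also account for the lists, with 16 of 57 calls, a median of 12 in the other groupings, 22 in the highest and 15 of 100 as large.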

How the results depend on the processing

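Summing copies and leaving out 3 doubted libraries were chosen after the data were seen, and all other settings were chosen beforehand. Of the values of named microRNAs, 132 were past the threshold. Of these, 93 stayed past it with the same sign in every setting chosen beforehand other than leaving out single libraries, and 92 without each library in turn. No paired analysis was possible because each library is a separate sample with no partner at another age in the labels. Leaving out hairpins with over 10% of reads, or keeping identical hairpins once, removed nothing at the level of hairpins; at family level 2 families were removed and 36 were called. Depth limits the oldest age most, where 42 months replicate 2 had 683884 reads.

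The count for the trend, 65, was 39 with a transgene term (36 of them among the 65) and 42 with copies summed, and the family count, 34, was 22 with a transgene term and 22 without the 3 doubted libraries. For 12 against 6 months, 10, it was 1 with upper-quartile scaling, 21 with DESeq2, 18 with limma-voom, 21 with only the 2 ages in the fit, 31 without the doubted libraries and 3 with copies summed. For 36 against 6 months, 65, it was 43 at a mean CPM of at least 100 and 37 with copies summed. Fewer items were tested with a CPM minimum or summed copies. With copies summed the TMM scaling also differed, and it moved the changes of hairpins without copies. For the other settings the cause was not tested. For 42 against 36 months, 10, it was 17 with DESeq2 size factors, 35 with DESeq2 and 0 with only the 2 ages in the edgeR fit (65 at an unadjusted p under 0.05; limma-voom on all ages called 9), and the cause was not tested. The 16 list calls became 0 with an estimated correlation, with or without copies summed, while fry called 22, and fry does not compare a list with other microRNAs. Numbers of detected hairpins did not differ at 1 count (permutation p = 0.281) but did at 10 (permutation p = 0.00474). Without the 3 doubted libraries the other counts were 102 for any difference, 50 for the trend, and 55, 87 and 42 for 24, 36 and 42 against 6 months, and 15 for 42 against 36 months.

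Without each library in turn, the counts ranged from 77 to 111 for any difference, from 42 to 69 for the trend (42 without 6 months replicate 4 or 5) and from 24 to 40 for families. They ranged from 1 to 12 for 12 against 6 months, from 43 to 76 for 24 (43 without 6 months replicate 5), from 54 to 69 for 36 and from 54 to 80 for 42 against 6 months. For 42 against 36 months they ranged from 1 (without 36 months replicate 4) to 29 (without 42 months replicate 4), with 4, 21 and 18 without 42 months replicates 1, 3 and 5. For 12 against 6 months the libraries that moved it were 6 months replicates 1 (1), 2 (1), 4 (2) and 5 (1), and 12 months replicates 1 (5), 2 (3), 3 (2), 4 (1) and 5 (6).

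No value past the threshold changed sign. The trend slopes below were not past it in either fit, and their sign changed; the cause was not tested. With DESeq2 size factors, let-7a-5 was 0.0026, let-7a-1 0.0012 and miR-15b 0.0073, and with DESeq2 they were 0.0025, 0.0012 and 0.0075. With upper-quartile scaling, miR-142b was -0.018, miR-199-1 -0.019, miR-199-2 -0.020, miR-204-2 -0.0052, miR-30d -0.047, miR-26a-3 -0.035, miR-26a-1 -0.035, miR-26a-2 -0.028 and miR-130c-2 -0.035. With library size only, miR-142b was -0.0062, miR-199-1 -0.0027, miR-199-2 -0.0041, miR-30d -0.030, miR-26a-3 -0.019, miR-26a-1 -0.019, miR-26a-2 -0.013 and miR-130c-2 -0.019. MiR-30d and miR-130c-2 were -0.0039 and -0.0035 with no filter and -0.031 and -0.0080 with limma-voom. With age group rank, miR-205 was 9.0e-04 and miR-130c-2 -0.0081. With log2 of age, miR-142b was -0.012, miR-143-1 0.011, miR-143-2 0.010 and miR-122 0.14. With a transgene term, miR-451 was 0.074, miR-143-1 0.042, miR-143-2 0.045, miR-9-4 -0.090, miR-9-6 -0.036 and miR-122 0.16. Without the 42-month group, miR-203b was 5.3e-05, miR-142b -0.0079, miR-122 0.30, miR-30d -0.11 and miR-130c-1 0.058. Without the doubted libraries, miR-25 was 0.014, miR-15b 0.048, miR-142a 0.013, miR-9-4 -0.020, miR-9-6 -0.013, miR-30d -0.025, miR-30e-2 0.0021 and miR-130c-1 0.021. With copies summed, miR-205 was 0.019, let-7a-1, let-7a-3 and let-7a-5 0.028, miR-25 0.020, miR-15b 0.030, miR-457a 3.6e-04, miR-451 0.0067, miR-143-1 and miR-143-2 0.024 and miR-130c-1 0.024. Of these, miR-205, miR-25, miR-15b, miR-457a and miR-451 have no copies to sum. Their own counts were the same in both fits, while the TMM scaling differed. By fry the direction of the Hox cluster and miR-26 lists at 42 against 6 months changed (adjusted p = 0.806 and 0.961).

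Without each library in turn, slopes of 19 microRNAs not past the threshold crossed 0. These ranged from -0.0096 to 0.032 for miR-130c-2, -0.033 to 0.022 for let-7a-5, -0.036 to 0.017 for let-7a-3, -0.033 to 0.021 for let-7a-1 and -0.066 to 0.053 for miR-30d. They ranged from -0.0055 to 0.037 for miR-26a-3, -0.0049 to 0.038 for miR-26a-1, -0.036 to 0.021 for miR-15b, -0.026 to 0.11 for miR-194a and -0.18 to 0.040 for miR-205. The ranges were -0.032 to 0.011 for miR-25, -0.038 to 0.020 for miR-143-1, -0.037 to 0.020 for miR-143-2, -0.031 to 0.010 for miR-130c-1 and -0.0047 to 0.053 for miR-199-1. Those of miR-199-2, miR-142b, miR-9-4 and miR-9-6 were -0.0064 to 0.051, -0.0099 to 0.048, -0.034 to 0.19 and -0.044 to 0.27.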

Other observations

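The test of neighbouring hairpins was chosen after the slopes were seen, and copies were summed in it after a result by hairpin was seen. The test of spread was planned.

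At 24 against 6 months, miR-101b was higher (log2 change 0.89 ± 0.24, SE, adjusted p = 0.0101), with 154.8 ± 24.4 CPM at 6 and 287 ± 176 at 24 months. It was not called without 24 months replicate 3, which held 596 CPM against 172 to 258 in the others. MiR-29a, of a family known to target collagens, was called higher by 0.53 ± 0.18 (adjusted p = 0.0362), 1 of 3 members, and all 3 were higher when adjusted over the list alone. Without 6 months replicates 1 or 4, or 24 months replicates 1, 3 or 4, 0 of the 3 were called by edgeR, and limma-voom called 0 of 3 on all libraries. DESeq2 called 3 of 3 there.

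Hairpins that lie next to each other in the genome may share a transcript and change alike. Neighbours were taken from the GRCz12tu gene table by name, in which 303 of 346 hairpins (87.6%) were matched. Over 41 pairs of names with different numbers whose hairpins lie within 10000 bases, 29 pairs had slopes of the same sign. Their mean absolute difference in slope was 0.13, against a median of 0.21 with slopes permuted among names (one-sided permutation p = 9.999e-04). By hairpin, with 43 pairs, the p was 5.0e-04. MiR-23a and miR-27a are such a pair, with slopes of 0.28 and 0.22, while miR-133b and miR-206 differed, with slopes of -0.09 and -0.43. Names that occur in several pairs are not independent, and pairs from one family were not separated from others.

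Old skin could vary more between libraries than young skin. Over 70 names of at least 1000 CPM the median SD of log2 CPM was 0.23 at 6 months, 0.27 at 12, 0.33 at 24, 0.22 at 36 and 0.31 at 42 months. The difference between 6 and 42 months gave an exact permutation p of 0.167 (two-sided, 252 splits of 10 libraries), so a rise in spread was not shown.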
